A study of Mus musculus with 16 samples.

How the data were processed

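RNA of mouse quadriceps was sequenced in 16 libraries of 4 groups of 4: healthy and injured (ACL transected) limbs of mice given placebo or CSF1-R inhibitor. Per the labels' protocols, mice drank the inhibitor at 40 mg/kg or 0.5% sucrose for 7 days after transection, and RNA was isolated with TRIzol and a column kit. The deposited table held expected counts per Ensembl gene, not normalized; per the submitters' processing notes, STAR, Partek and DESeq2 were used with GRCm38/mm10, with no role, order or version given. Of the deposited values, 33.8% were not whole numbers and 24.2% differed from a whole number by over 0.01. Each of the 17370 genes reached a count of 10 or more in at least 1 library, as the smallest maximum of a gene was 10. The annotation release is not stated in the labels; symbols and coordinates were taken from GENCODE M21 by Ensembl ID, which gave 17338 genes a symbol and left 32 without, with 15 duplicate symbols.

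Counts were rounded to whole numbers. Library totals were 20.12 to 27.13 M (mega), 16560 to 17054 genes had a count above 0, the 10 most abundant genes took 22.51 to 27.54% of the counts and mitochondrial genes 10.69 to 18.98%. No 2 libraries were identical, and any 2 differed in at least 96% of genes. EdgeR 4.0.16 in R 4.3.3 removed 1959 genes with filterByExpr (minimum count 10), scaled libraries by TMM and fitted 4 group means to all 16 libraries with the robust quasi-likelihood method (common biological coefficient of variation 0.284, 12 residual degrees of freedom). The 5 comparisons were injury with placebo, injury with inhibitor, inhibitor in injured quadriceps, inhibitor in healthy quadriceps, and the difference of the injury effects, each two-sided with Benjamini-Hochberg adjustment over 15411 genes at 0.05. The p values measure the spread between these samples, as far as the labels say what a sample is. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

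Gene lists were written before the data were examined, as were the comparisons, the tests and the first set of alternatives. There were 37 lists with 788 genes, of which 762 were in the table, and the 35 lists with at least 5 tested members entered camera (limma 3.58.1, on voom values) with its preset correlation of 0.01, with an estimated correlation, and fry. The T and NK cell list kept 3 tested members (Cd3e, Cd2 and Thy1) and the mast cell list 4 (Cma1, Mcpt4, Cpa3 and Tpsb2), and neither was tested. Genes were to be named by a fixed rule: the 5 highest and 5 lowest log2 fold changes among called genes with a mean log2 CPM of 1 or more whose groups do not overlap (no separation asked for the difference of injury effects), leaving out predicted genes, the 3 members with the smallest p of each list called by camera or with at least 3 called members, and 16 fixed genes in every comparison. No gene was called, so the first of these parts named none. The genes printed are a subset of those the rule names, picked after their values were seen; Prg4, Col2a1, Dbp, Arntl and Nfil3 were also chosen after their values were seen.

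The names of the libraries join a healthy and an injured quadriceps by a shared stem, which was read as 1 animal, while the deposited design text speaks of before and after. The correlation of the deviations of such pairs from their group means was 0.23, -0.04, -0.01 and -0.10 for inhibitor animals 1 to 4 and 0.47, -0.18, -0.11 and -0.53 for placebo animals 1 to 4. Over clock genes alone it was 0.76, 0.67, 0.72, 0.25, 0.88, 0.11, 0.72 and 0.62 in the same order. The animal was fitted as a block in an alternative, with 6 residual degrees of freedom, and limma's correlation within animals was 0.016.

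Alternatives were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, limma-voom with quality weights, limma-voom with the correlation within animals, only the 8 libraries compared, the animal or the replicate number as a block, and each library left out in turn. The filter on low counts was rerun in each fit that leaves out libraries, so the tested members of lists could differ between fits. Chosen after seeing the data were fits without both libraries of each animal, without the 3 libraries highest in macrophage markers, tried first and for the count of genes alone, and without the 4 highest in joint markers, chosen later.

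Each comparison was tested on simulated counts with 200 changed genes and 15195 to 15235 genes tested. For injury with placebo 46.5% of genes changed 2-fold and 75.8% of those changed 4-fold were recovered, with 7 of 140 calls false. The same values were 47% and 73.7% with 3 of 130 false for injury with inhibitor, 60.6% and 79% with 4 of 149 for the inhibitor in injured quadriceps, 50.5% and 78.4% with 6 of 138 for the inhibitor in healthy quadriceps, and 28% and 64% with 4 of 98 for the difference. Of 100 lists of unchanged genes, camera gave an unadjusted p under 0.05 to 3, 1, 1, 1 and 2 in this order. Simulated genes were drawn independently, so these shares cannot show how camera behaves on lists of genes that vary together. A further set of genes with a smaller shift was simulated, and calls of these were not counted as false.

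The labels do not state whether counting used the strand of reads, so genes that overlap or share reads with close copies are uncertain. Of the tests in the closing part, the joint tissue test of the macrophage pattern was first an exact rank comparison of libraries, replaced after its value was seen because it grouped libraries by a measured outcome. The bounds of the time-of-day test were set after its value was seen. Both tests of the clock pattern first used an index whose genes had been signed after their directions were seen, and were replaced for that reason by tests on all clock genes without signs.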

Results

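Total RNA of mouse quadriceps, the thigh muscle that extends the knee, was sequenced in 16 libraries. The anterior cruciate ligament (ACL) of the knee was transected in 1 limb, and the mice then drank an inhibitor of CSF1-R, the receptor through which macrophages receive their survival signal, at 40 mg/kg, or a placebo of 0.5% sucrose, for 7 days. Each of the 4 groups held 4 libraries: healthy and injured quadriceps, with placebo or with inhibitor. The library names join a healthy and an injured quadriceps of each of 8 animals, and libraries are named here by group and replicate number. Of the genes in the deposited table, 15411 were tested. Levels are given as CPM, the usual library-size-scaled counts. A floor of 3 counts corresponded to 0.109 to 0.159 CPM, and such floors cover counting error only. Levels are the mean ± SD over the 4 libraries of a group, log2 differences of genes carry their standard error (SE), and values of gene lists are means of the log2 differences of their members.

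The genes followed throughout were placed on GRCm38 with the GENCODE annotation. Csf1r (ENSMUSG00000024621), which encodes the target of the inhibitor, lies on chromosome 18 from 61100598 to 61132149. Ccr2 (ENSMUSG00000049103), a chemokine receptor of monocytes, lies on chromosome 9 from 124101950 to 124113557. C1qa (ENSMUSG00000036887), a complement gene of macrophages, lies on chromosome 4 from 136895917 to 136898803. Myog (ENSMUSG00000026459), a transcription factor of myogenic differentiation that muscle also expresses after loss of its nerve supply, lies on chromosome 1 from 134289989 to 134292548. Chrna1 (ENSMUSG00000027107), a subunit of the muscle acetylcholine receptor, lies on chromosome 2 from 73563215 to 73580338. Col1a1 (ENSMUSG00000001506), a collagen gene, lies on chromosome 11 from 94936224 to 94953042. Cox5a (ENSMUSG00000000088), a subunit of cytochrome c oxidase, lies on chromosome 9 from 57521274 to 57532426. Per2 (ENSMUSG00000055866), a repressor of the circadian clock, lies on chromosome 1 from 91415982 to 91459324.

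Some markers of cartilage and joint lining stood apart in 4 libraries. Prg4, which encodes the lubricin of joint surfaces, was at 251 CPM in healthy placebo 4, 220 in injured placebo 2, 286 in injured placebo 3 and 169 in healthy inhibitor 1, and at 3.97 to 19.5 CPM in the other 12 libraries. Col2a1, the main collagen of cartilage, was at 7.58, 2.44, 2.73 and 1.78 CPM in these 4 libraries in the same order. Their scores for the list of such markers were 2.08, 1.22, 1.56 and 1.59 on the log2 scale, and those of the other libraries were below 0. Col10a1 also went with these 4 libraries, at 0.4 to 1.64 CPM against at most 0.165. Col11a2, Col9a1 and Cytl1 did not set them apart. Col11a2 was at 4.21 CPM in healthy inhibitor 1 against 5.41 in healthy placebo 3. Col9a1 was at 0.0802 in injured placebo 3, and Cytl1 at 0.436 in injured placebo 2 against 3.18 in injured inhibitor 4. Results without these 4 libraries are given beside the groups of genes they move with, in fits chosen after seeing the data. In those fits injured placebo 1 and 4 alone stand for their group, and both healthy groups lose a library. The low-count filter was rerun in them, and camera was run with the preset correlation only.

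**Figure D1:**
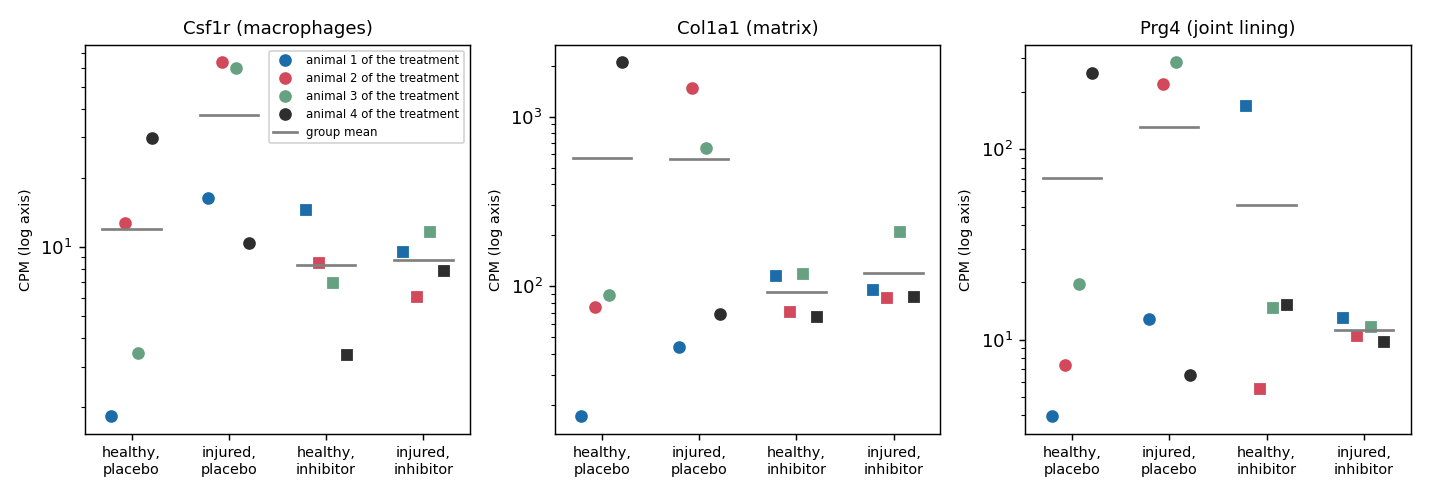
Levels of Csf1r, Col1a1 and Prg4 in CPM (vertical log axes) in each of the 16 libraries, by group; each point is 1 library, colours mark the animal within a treatment, circles are placebo, squares are inhibitor and grey lines are group means. Healthy placebo 4 lay at 2090 CPM of Col1a1 and 251 CPM of Prg4, with injured placebo 2 and 3 and healthy inhibitor 1 also above 100 CPM of Prg4.

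Injured was first compared with healthy quadriceps under placebo, which asks what the injury did to muscle of untreated animals. Genes of macrophages were higher in the injured limb: all 30 tested members of the macrophage list had positive log2 differences, with a mean of 1.57. Csf1r averaged 12 ± 12.9 CPM in healthy and 37.7 ± 28.2 CPM in injured quadriceps (SD, n = 4), a log2 difference of 1.66 ± 0.79, and Tyrobp, an adaptor of myeloid cell receptors, gave 2.25 ± 0.95. All 9 monocyte markers were higher, with a mean of 1.11, among them Ccr2 at 6.09 ± 7.65 and 28.7 ± 27.1 CPM. Of 13 genes of dendritic cells and MHC class II, which presents antigen to helper T cells, 12 were higher, with a mean of 1.55; H2-DMa, which loads peptides onto class II molecules, averaged 2.68 ± 1.61 and 8.32 ± 5.35 CPM.

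Camera with its preset correlation placed the macrophage list past its threshold at adjusted p = 4.8e-12, the monocyte list at 0.0015 and the class II list at 9.4e-09. For each of these 3 lists, adjusted p = 0.37 with an estimated correlation, so that none was called. Each had a higher score in the injured limb of 3 of 4 animals. The other animal was placebo animal 4, whose macrophage score was 1.94 in the healthy and -0.14 in the injured limb. Without healthy placebo 4, the 3 means were 3.13, 2.49 and 2.41. The monocyte mean was also 0.73 without healthy placebo 1, 0.70 without healthy placebo 3 and 0.55 without injured placebo 2. With the 4 libraries high in joint markers left out, the macrophage mean was 1.11, that of monocytes 1.05 and that of class II 1.16, all still past the threshold. When adjusted over the list alone, edgeR called 2 class II genes and no gene of the other 2 lists.

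Further lists of immune function moved the same way. All 24 interferon-stimulated genes were higher (mean 0.85), as were all 27 genes of lysosome and phagocytosis (0.96), 13 of 14 complement genes (0.75) and 16 of 17 cytokines and chemokines (0.98). Examples were the antiviral membrane protein gene Bst2 (log2 difference 1.22 ± 0.43), the lysosomal enzyme gene Hexa (0.42 ± 0.14), the central complement gene C3 (0.96 ± 0.44) and the interferon-induced chemokine gene Cxcl10, at 0.206 ± 0.217 CPM in healthy and 2.35 ± 1.48 CPM in injured quadriceps (SD, n = 4). Camera adjusted p values were 1.3e-09, 9.4e-09, 1.6e-05 and 1.6e-05, with the direction in 3 of 4 animals, and adjusted p = 0.37 with an estimated correlation for all 4 lists. Adjusted over the list alone, 1 cytokine gene passed. Without healthy placebo 4, the means of complement, lysosome and cytokine genes were 1.38, 1.76 and 2.00, and without injured placebo 2 those of interferon, lysosome and cytokine genes were 0.52, 0.63 and 0.61. When the 4 libraries high in joint markers were left out, interferon genes averaged 0.32 and lysosome genes 0.47, both past the threshold.

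Neutrophil markers, 5 genes of low count, had a mean of 0.64 with 3 members higher and 2 lower, at camera adjusted p = 0.032 and adjusted p = 0.44 with an estimated correlation, with the direction in 3 of 4 animals. Without healthy placebo 1, 2 or 3 the means were -0.43, -0.40 and -0.46, none past the threshold. Without injured placebo 1, 2, 3 or 4 they were 0.12, -0.32, 0.18 and 0.26, also not past it, and without healthy placebo 4 the mean was 2.81. The low-count filter was rerun in each of these fits, so the tested members could change. With all libraries and no such filter the mean was -0.23 (camera adjusted p = 0.4). The lost calls thus cannot be put down to the library left out. With the animal as a block, the adjusted p of this list was 0.22.

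Genes of myogenesis and denervation were higher in the injured limb. Of 20 satellite cell and myogenesis genes, 17 were higher, with a mean of 0.90 and a median of 0.36. Myog averaged 4.16 ± 1.13 CPM in healthy and 21.7 ± 20.6 CPM in injured quadriceps (SD, n = 4), a log2 difference of 2.39 ± 0.66, and Myh3, the embryonic myosin heavy chain of newly formed fibres, 6.04 ± 5.42 and 103 ± 119 CPM, a log2 difference of 4.10 ± 1.14. Of 19 denervation-responsive genes, 14 were higher, with a mean of 0.91. Chrna1 averaged 14.2 ± 3.87 and 36.2 ± 18.1 CPM, Musk, a kinase that clusters acetylcholine receptors, 4.09 ± 0.953 and 7.05 ± 0.95 CPM, and Rrad, a small GTPase of muscle, 1.38 ± 0.479 and 12.4 ± 10.7 CPM. Cell cycle genes were higher for 26 of 28 members with a mean of 1.11, and the licensing factor gene Mcm4 averaged 4.50 ± 0.474 and 7.01 ± 1.45 CPM.

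Camera gave adjusted p = 0.00088 for myogenesis and 0.001 for denervation, each with adjusted p = 0.37 with an estimated correlation, and 1.6e-05 for the cell cycle, with adjusted p = 0.44 with an estimated correlation. The direction held in 3 of 4 animals. When adjusted over the list alone, 6 myogenesis, 7 denervation and no cell cycle genes passed edgeR's test. Injured placebo 2 and 3, the libraries highest in joint markers in this group, also had the highest denervation scores, 1.02 and 1.04 against 0.22 and -0.48 in injured placebo 1 and 4. In fits that lacked the 4 libraries high in joint markers, neither list was past the threshold: the myogenesis mean was 0.12 (adjusted p = 0.48) and the denervation mean 0.22 (adjusted p = 0.19). The cell cycle mean was -0.12 without these 4 (adjusted p = 0.65), 0.52 without injured placebo 2 and 1.96 without healthy placebo 4.

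The muscle's own atrophy genes showed no such difference. Of 28 atrophy genes, 13 were higher and 15 lower, with a mean of 0.09, a median of -0.04 and camera adjusted p = 0.78. Fbxo32 and Trim63, ubiquitin ligases that mark muscle proteins for degradation, had log2 differences of -0.19 ± 0.35 and 0.04 ± 0.21, and Mstn, an inhibitor of muscle growth, -0.17 ± 0.24. Proteasome subunit genes averaged 0.02 (adjusted p = 0.45). Autophagy genes were lower for 19 of 23 members with a mean of -0.06, at adjusted p = 0.041 and adjusted p = 0.44 with an estimated correlation, in 3 of 4 animals. That call was lost without the 4 libraries high in joint markers (-0.01) and also without healthy placebo 1 (-0.03), healthy placebo 3 (-0.04), injured placebo 2 (-0.03) or injured placebo 3 (-0.03), and the mean was -0.11 without injured placebo 1 and -0.10 without healthy placebo 4.

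Contractile and metabolic genes of the fibres differed as well. All 19 fast-twitch genes were lower (mean -0.23), with Myh4, the myosin of the fastest fibres, at 58200 ± 17200 and 46700 ± 15400 CPM (SD, n = 4), and 22 of 24 glycolysis genes were lower (mean -0.18), with Slc2a4, the insulin-dependent glucose transporter, at a log2 difference of -0.28 ± 0.10. All 46 genes of oxidative phosphorylation were lower (mean -0.15), for example Uqcrfs1 (-0.22 ± 0.11) and Cox5a (-0.21 ± 0.11), as were 16 of 17 genes of the tricarboxylic acid cycle (-0.14) and 13 of 15 mitochondrially encoded genes (-0.17). Slow-twitch genes were higher for 16 of 17 members (mean 0.81), although Myh7, the slow myosin, varied from library to library, at 295 ± 330 and 607 ± 636 CPM.

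Camera gave adjusted p = 9.8e-05 for fast-twitch, 3.9e-06 for glycolysis, 3.2e-06 for oxidative phosphorylation, 9.3e-05 for the tricarboxylic acid cycle, 0.0041 for mitochondrially encoded and 0.018 for slow-twitch genes. The adjusted p = 0.37 with an estimated correlation for the first 2 lists, 0.44 for the next 2, 0.49 for mitochondrially encoded and 0.62 for slow-twitch genes. The direction held in 3 of 4 animals for fast-twitch and glycolysis genes and in 2 of 4 for the other lists. Fatty acid oxidation genes and oxidative regulators averaged -0.05 with 20 of 30 lower (adjusted p = 0.038, and adjusted p = 0.70 with an estimated correlation, in 2 of 4 animals), and their mean was above 0 without healthy placebo 2 (0.04), injured placebo 2 (0.09) or injured placebo 3 (0.01), with the call lost. Without the 4 libraries high in joint markers their call was reversed (0.16, adjusted p = 0.0034). Without healthy placebo 3, the means of fast-twitch, glycolysis and oxidative phosphorylation genes were -0.10, -0.10 and -0.06. Without injured placebo 1, those of the tricarboxylic acid cycle, mitochondrially encoded and fatty acid oxidation genes were -0.26, -0.46 and -0.23, and without healthy placebo 4 they were -0.22, -0.30 and -0.12, with oxidative phosphorylation at -0.23. Without healthy placebo 2, the tricarboxylic acid cycle averaged -0.05, mitochondrially encoded genes -0.02 with the call lost, and slow-twitch genes 1.51. Without injured placebo 2, the calls for the cycle (-0.04) and for mitochondrially encoded genes (-0.02) were lost. Mitochondrially encoded genes averaged -0.10 without injured placebo 3, and without injured placebo 4 fast-twitch genes averaged -0.36, glycolysis genes -0.27 and fatty acid oxidation genes -0.10. The slow-twitch call was lost without healthy placebo 1 (0.57), healthy placebo 4 (0.67), injured placebo 1 (0.73) or injured placebo 3 (0.30). Without the 4 libraries high in joint markers, it was lost as well (-0.05), as were those of the cycle (-0.02) and of mitochondrially encoded genes (0.01).

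Genes of the connective tissue were also higher. All 16 markers of fibro-adipogenic progenitors, the resident mesenchymal cells of muscle, were higher (mean 0.41), with Pdgfra, their surface receptor, at 24.7 ± 14.3 and 38.7 ± 7.48 CPM (SD, n = 4). Of 47 genes of the extracellular matrix, 43 were higher (mean 0.42), but Col1a1 averaged 569 ± 1020 and 559 ± 669 CPM, with 2090 CPM in healthy placebo 4, the library highest in joint markers, against 17.2 to 88.5 CPM in the other 3. All 11 tendon markers were higher (0.65), as were 43 of 45 ribosomal protein genes (0.22) and 20 of 25 immediate early and heat shock genes (0.26), and 13 of 15 endothelial markers were lower (-0.17), among them Esam, an adhesion molecule of vessel walls (-0.37 ± 0.11).

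Camera gave these 6 lists adjusted p values of 1.6e-05, 3.9e-06, 0.0048, 1.6e-05, 0.0013 and 0.001 in this order. With an estimated correlation the adjusted p values were 0.37, 0.44, 0.44, 0.44, 0.37 and 0.37. The direction held in 3 of 4 animals, or in 2 of 4 for ribosomal and endothelial genes. The matrix mean was -0.15 without injured placebo 2, where camera still called the list as higher (adjusted p = 0.018), 1.98 without healthy placebo 4, 0.14, 0.22 and 0.18 without healthy placebo 1, 2 or 3, and 0.65 and 0.67 without injured placebo 1 or 4. The progenitor mean was 0.20 without healthy placebo 1, 0.26 without healthy placebo 3 or injured placebo 3, and 0.84 without healthy placebo 4. The tendon call was lost without healthy placebo 1 (0.37), injured placebo 2 (0.33) or injured placebo 3 (0.43), and the ribosomal call without injured placebo 3 (0.09), with 0.09 also without injured placebo 2. The immediate early call was lost without injured placebo 2 (0.12), with means of 0.15 without healthy placebo 3 and 0.40 without injured placebo 4, and the endothelial mean was -0.29 without injured placebo 1 and -0.09 without injured placebo 3. With the 4 libraries high in joint markers left out, the ribosomal call was reversed (-0.16, adjusted p = 0.01) and the calls of tendon (-0.04), endothelial (-0.05) and immediate early genes (0.09) were lost.

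The remaining lists were not past the threshold in this comparison: B cell and plasma cell markers (mean -0.39, adjusted p = 0.97), cartilage and joint lining markers (0.02, 0.97), adipocyte markers (0.53, 0.97), pericyte and smooth muscle markers (-0.11, 0.055), Schwann cell and nerve markers (-0.01, 0.75), red blood cell genes (0.15, 0.97), genes of the unfolded protein and integrated stress responses (0.21, 0.055) and circadian clock genes (-0.06, 0.14). With the animal as a block, the pericyte and clock lists passed at adjusted p = 0.044 and 0.032. Adipocyte (1.43) and mast cell markers (0.99) were called without the 4 libraries high in joint markers. Median, mean and test differed in sign for the B cell, red blood cell and atrophy lists. In total camera called 25 of 35 lists, 17 higher and 8 lower, none of them with an estimated correlation or by fry's directional test, whose smallest adjusted p was 0.23.

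No single gene passed adjusted p 0.05 in edgeR's test of the placebo groups (0 of 15411, smallest adjusted p = 0.641, for Apod). At unadjusted p under 0.05 there were 1116 genes, 710 higher and 406 lower, where chance gives 771, and DESeq2 and limma-voom with quality weights each called 0. Without injured placebo 4 the count was 3, and without both libraries of placebo animal 4 it was 971, of which 816 were higher and 155 lower.

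Injured and healthy quadriceps were then compared under the inhibitor, which asks what the injury did while CSF1-R was blocked. With all libraries, no immune list was past the threshold. The macrophage list averaged -0.01 with 18 members higher and 12 lower (camera adjusted p = 0.74), neutrophil and B cell markers averaged -1.12 and -0.61 (adjusted p = 0.67 and 0.46), and Csf1r averaged 8.34 ± 4.63 CPM in healthy and 8.75 ± 2.38 CPM in injured quadriceps (SD, n = 4). Without healthy inhibitor 1, high in joint markers, the macrophage mean was 0.49 (adjusted p = 0.28) and the neutrophil mean 0.47 (0.77). The macrophage mean was 0.53 and past the threshold (adjusted p = 0.0023) without the 4 libraries high in joint markers, with monocytes at 0.56 (0.12) and cytokines at 0.35 (0.57). Interferon-stimulated genes averaged -0.15, and were called without healthy inhibitor 2 (-0.25) or 4 (-0.26). Myog was at 5.47 ± 1.11 and 4.90 ± 1.67 CPM, and the satellite cell and denervation lists averaged 0.05 and 0.16 (adjusted p = 0.69 and 0.59). Slow-twitch genes were higher for 16 of 17 members (mean 0.62), for example Casq2, a calcium store protein of slow fibres, at 30.9 ± 21 and 55.7 ± 23.4 CPM, and fast-twitch genes were lower for 17 of 19 (mean -0.13), although Myh1, a fast myosin, was at 5830 ± 1470 and 8240 ± 1410 CPM. Genes of fatty acid oxidation were higher for 28 of 30 (mean 0.24), with Ppargc1a, a coactivator that drives mitochondrial gene expression, at 30.8 ± 2.68 and 38.7 ± 4.20 CPM, as were 38 of 46 genes of oxidative phosphorylation (0.08) and all 17 of the tricarboxylic acid cycle (0.12). Proteasome subunit genes were lower for 31 of 33 (mean -0.07) and atrophy genes for 22 of 28 (-0.08), with Fbxo32 at 548 ± 117 and 414 ± 172 CPM and Trim63 at 190 ± 24 and 149 ± 28.3 CPM.

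These 7 lists, 4 higher and 3 lower, were past camera's threshold, at adjusted p = 8.7e-06 for slow-twitch, 0.00064 for fast-twitch, 1.5e-10 for fatty acid oxidation, 0.00062 for oxidative phosphorylation, 0.0018 for the cycle, 5.8e-05 for the proteasome and 0.045 for atrophy genes. For each of them, adjusted p = 0.92 with an estimated correlation. The direction held in 4 of 4 animals for fatty acid oxidation and atrophy genes, in 2 of 4 for oxidative phosphorylation and in 3 of 4 for the other 4 lists. No gene passed when adjusted over the list alone. Healthy inhibitor 1 was high in joint markers, and without it the slow-twitch mean was 1.19 and that of oxidative phosphorylation 0.14. The slow-twitch mean was 0.35 without injured inhibitor 1, 0.37 without healthy inhibitor 4 and 0.32 without healthy inhibitor 2, which ended the call. The oxidative phosphorylation call was lost without injured inhibitor 1 (0.02), injured inhibitor 2 (0.03), healthy inhibitor 2 (0.04) or healthy inhibitor 4 (0.04), and its mean was 0.14 without injured inhibitor 4. The atrophy call was lost without healthy inhibitor 1 (-0.05), healthy inhibitor 4 (-0.05), injured inhibitor 2 (-0.07) or injured inhibitor 3 (-0.03), and, without the 4 libraries high in joint markers, at a mean of -0.06. The call of the cycle was lost without injured inhibitor 1 (0.09), healthy inhibitor 2 (0.08) or injured inhibitor 2 (0.08), its mean was 0.18 without healthy inhibitor 1, and the proteasome mean was -0.11 without injured inhibitor 1.

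Besides macrophage markers, 6 more lists were called without the 4 libraries high in joint markers. These were matrix (0.28), red blood cell (0.71), mitochondrially encoded (0.18), ribosomal (0.09), immediate early (0.20) and mast cell genes (0.93). The mast cell list, too short to be tested with all libraries, was called in each of the 7 fits without 1 library that could test it (means of 0.56 to 1.11). Median, mean and test differed in sign for the macrophage, class II, cytokine, adipocyte, pericyte, satellite cell and stress response lists, none of them past the threshold. Of single genes, edgeR called 0 of 15411 between injured and healthy quadriceps with inhibitor (smallest adjusted p = 1), with 202 genes at unadjusted p under 0.05, 118 higher and 84 lower. Chance gives 771 such genes. DESeq2 called 1 and limma-voom with quality weights 0.

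**Figure D2:**
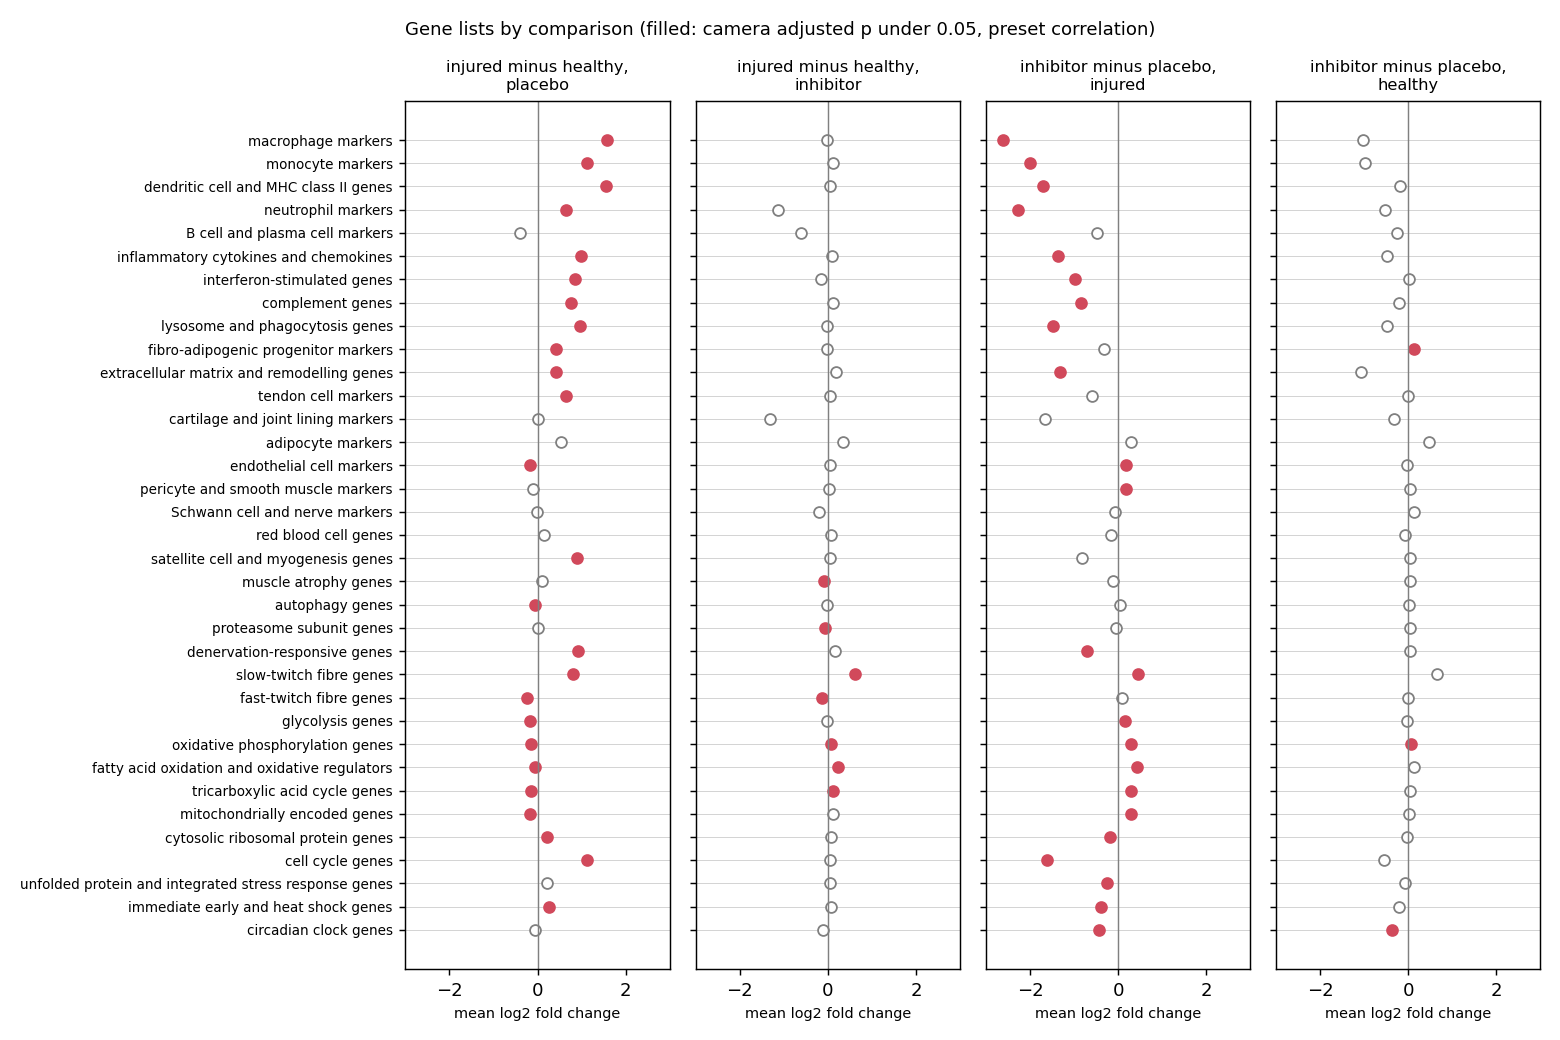
Mean log2 fold change of the members of each of 35 gene lists (horizontal axis, log2 units) in 4 comparisons of 4 against 4 libraries; each circle is 1 list, and filled circles passed camera's adjusted p of 0.05 with the preset correlation, none of which passed with an estimated correlation. The macrophage list lay at 1.57 for injured minus healthy with placebo, -0.01 with inhibitor, and -2.60 for inhibitor minus placebo in injured quadriceps.

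Inhibitor was compared with placebo within injured quadriceps, which asks what CSF1-R inhibition changed in the injured limb. All 30 macrophage markers were lower with the inhibitor (mean -2.60): Csf1r averaged 37.7 ± 28.2 CPM with placebo and 8.75 ± 2.38 CPM with inhibitor (SD, n = 4), a log2 difference of -2.10 ± 0.81, Adgre1, which encodes the F4/80 antigen, 14.4 ± 13.1 and 1.70 ± 1.03 CPM, Cd68, a lysosomal protein of macrophages, 12.3 ± 12.5 and 1.00 ± 0.589 CPM, and C1qa 32.4 ± 31.6 and 5.35 ± 2.15 CPM. Mrc1, the mannose receptor of resident macrophages, differed by -1.53 ± 0.48. All 9 monocyte markers were lower (-1.99), with Ccr2 at 28.7 ± 27.1 and 3.59 ± 2.83 CPM. The genes of the receptor's ligands, Csf1 and Il34, differed by -0.31 ± 0.30 and -0.26 ± 0.24.

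Camera gave adjusted p = 9.3e-10 for macrophage and 0.0045 for monocyte markers, with all 4 inhibitor libraries below the placebo mean and adjusted p = 0.42 with an estimated correlation for both. Adjusted over the list alone, 26 macrophage and 3 monocyte markers passed edgeR's test. Injured placebo 2 and 3 held the highest macrophage scores, 2.85 and 2.63, and were both high in joint markers, while injured placebo 1 and 4 were at 0.25 and -0.14 and the inhibitor libraries between -1.06 and 0.05. When the 4 libraries high in joint markers were left out, the macrophage mean was -0.52 (adjusted p = 2.4e-05) and the monocyte mean -0.44, no longer past the threshold (adjusted p = 0.14).

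Other immune lists were lower as well, although B cell and plasma cell markers were not past the threshold (mean -0.48, 4 of 6 lower, adjusted p = 0.90). Lysosome and phagocytosis genes were lower for all 27 members (-1.48), class II genes for 12 of 13 (-1.70), interferon-stimulated genes for 23 of 24 (-0.98), cytokines and chemokines for 16 of 17 (-1.37), complement genes for 12 of 14 (-0.83) and neutrophil markers for all 5 (-2.28). H2-Ab1, a class II chain, averaged 53.0 ± 41.9 and 12.6 ± 5.14 CPM (SD, n = 4), and Rnf213, an interferon-induced ubiquitin ligase, 36.1 ± 11.8 and 24.2 ± 1.59 CPM. Camera adjusted p values were 4.1e-10, 3.6e-06, 1.9e-07, 8.1e-05, 0.0017 and 0.033 in this order, with adjusted p = 0.42 with an estimated correlation for all 6 and all 4 inhibitor libraries below the placebo mean. When adjusted over the list alone, 18 lysosome, 7 class II and 7 interferon genes passed. The neutrophil call was lost without injured placebo 2 (-1.31), and its mean was -3.92 to -3.56 in the 7 other fits without 1 library. Tested members could change, as the low-count filter was rerun, so these shifts from -2.28 cannot be put down to the library left out. Without injured placebo 2 the interferon mean was -0.64. In fits that lacked the 4 libraries high in joint markers, lysosome genes averaged -0.23, class II genes -0.43 and complement genes -0.37, all past the threshold, and the calls of interferon (-0.03) and cytokine genes (-0.36) were lost.

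Genes of mitochondrial energy metabolism were higher with the inhibitor. All 46 genes of oxidative phosphorylation were higher (mean 0.30), with Cyc1, of respiratory complex III, at 263 ± 22.6 CPM with placebo and 351 ± 30.7 CPM with inhibitor (SD, n = 4) and Cox5a at 209 ± 20 and 278 ± 32.6 CPM. Fatty acid oxidation genes and oxidative regulators were higher for 29 of 30 (0.42), among them Esrra, a nuclear receptor that controls mitochondrial genes (69.7 ± 11.6 and 97.3 ± 7.49 CPM), and Acadvl, the very long chain acyl-CoA dehydrogenase (log2 difference 0.52 ± 0.15). All 17 genes of the tricarboxylic acid cycle were higher (0.30), with Dlat, of pyruvate dehydrogenase, at 162 ± 23.4 and 219 ± 13.8 CPM, as were 14 of 15 mitochondrially encoded genes (0.30), 22 of 24 glycolysis genes (0.15) and 16 of 17 slow-twitch genes (0.46).

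Camera adjusted p values were 9.1e-17, 2.7e-13, 1.8e-09, 5.9e-05, 0.00071 and 0.022 in this order, with adjusted p = 0.42 with an estimated correlation for the first 5 lists and 0.66 for slow-twitch genes. Against the placebo mean, the direction held in all 4 inhibitor libraries, or in 3 for slow-twitch genes. Adjusted over the list alone, 5 oxidative phosphorylation, 11 fatty acid oxidation and 3 cycle genes passed. Without the 4 libraries high in joint markers, the first 3 means were 0.22, 0.15 and 0.10, glycolysis was at 0.16 and slow-twitch genes at 1.19, all past the threshold, and mitochondrially encoded genes were not (0.00). They averaged 0.18 without injured inhibitor 2, 0.60 without injured placebo 1 and 0.16 without injured placebo 2. The glycolysis call was lost without injured placebo 1 (0.10), and its mean was 0.23 without injured placebo 4. The slow-twitch call was lost without injured inhibitor 1 (0.19), 2 (0.36) or 3 (0.47) or injured placebo 4 (0.17), with means of 0.77 without injured inhibitor 4 and 0.97 without injured placebo 3.

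Matrix, cell cycle and denervation genes were lower with the inhibitor. Of 47 matrix genes, 45 were lower (mean -1.31); Col1a1 averaged 559 ± 669 CPM with placebo and 119 ± 59.4 CPM with inhibitor (SD, n = 4), and Cthrc1, a secreted protein of remodelling matrix, 15.1 ± 20.8 and 0.453 ± 0.444 CPM. Cell cycle genes were lower for 27 of 28 (-1.61), with Mcm4 at 7.01 ± 1.45 and 4.07 ± 0.765 CPM, and denervation-responsive genes for 17 of 19 (-0.71), with Chrna1 at 36.2 ± 18.1 and 17.1 ± 2.82 CPM and Myog at 21.7 ± 20.6 and 4.90 ± 1.67 CPM. Ribosomal protein genes were lower for 41 of 45 (-0.18), stress response genes for 17 of 22 (-0.24) and immediate early and heat shock genes for 20 of 25 (-0.38), with the transcription factor gene Klf6 at 33.3 ± 7.03 and 20.2 ± 1.54 CPM. Endothelial markers were higher for 12 of 15 (0.18) and pericyte and smooth muscle markers for 10 of 13 (0.17). The satellite cell and myogenesis list, which also holds Myog, was not past the threshold (mean -0.82, 14 of 20 lower, adjusted p = 0.085). It was called without injured inhibitor 3 (-1.28), injured placebo 1 (-1.18) or injured placebo 4 (-1.17), and its mean was 0.10 without the 4 libraries high in joint markers. Atrophy genes were not past the threshold (mean -0.11, adjusted p = 0.63), with Fbxo32 at -0.41 ± 0.35 and Trim63 at -0.40 ± 0.21.

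Camera gave these 8 lists adjusted p values of 0.00011, 1.2e-05, 0.007, 0.00068, 0.017, 0.013, 0.0019 and 0.034 in the order named. With an estimated correlation adjusted p values were 0.62 for matrix and ribosomal genes, 0.44 for immediate early genes and 0.42 for the other 5. All 4 inhibitor libraries lay on the called side of the placebo mean. Yet injured placebo 1 and 4 lay below all 4 for matrix and ribosomal genes. When adjusted over the list alone, 2 cell cycle genes and 1 immediate early gene passed. Injured placebo 2 and 3, high in joint markers, held 1470 and 656 CPM of Col1a1 against 44.2 and 68.7 CPM in injured placebo 1 and 4. With the 4 libraries high in joint markers left out, the calls of matrix (0.30, adjusted p = 0.0021) and ribosomal genes (0.23, 0.00037) were reversed. The cell cycle mean was 0.28 (0.36) and the endothelial mean 0.00 (0.95), neither past the threshold, and the calls of denervation (0.08), pericyte (0.18), stress response (-0.13) and immediate early genes (-0.11) were lost. Without injured placebo 2 the calls of matrix (-0.73), ribosomal (-0.04) and immediate early genes (-0.24) were lost and the cell cycle mean was -1.01. Without injured placebo 1 the immediate early (-0.30) and pericyte (0.18) calls were lost, and the denervation, endothelial and ribosomal means were -1.09, 0.31 and -0.28. Without injured placebo 3 the ribosomal (-0.05) and pericyte (0.14) calls were lost and the endothelial mean was 0.11, and without injured placebo 4 the denervation, stress response and ribosomal means were -1.22, -0.37 and -0.27. Without injured inhibitor 3 the immediate early (-0.32) and pericyte (0.16) calls were lost and the denervation mean was -1.12, and without injured inhibitor 4 the pericyte call was lost (0.11) and the stress response mean was -0.40.

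Circadian clock genes differed in both directions. Per1 averaged 38.8 ± 9.97 CPM with placebo and 15.1 ± 5.04 CPM with inhibitor in injured quadriceps (SD, n = 4), a log2 difference of -1.36 ± 0.27, and Per2 7.38 ± 2.94 and 2.67 ± 0.732 CPM, a difference of -1.47 ± 0.35. Cry1, a repressor that peaks later in the cycle, was at 12.3 ± 1.45 and 22.8 ± 2.75 CPM, a difference of 0.89 ± 0.17. Of the 17 clock genes, 11 were lower and 6 higher (mean -0.44). Adjusted over the list alone, 8 lower and 2 higher passed edgeR's test. Camera gave adjusted p = 0.041 and adjusted p = 0.42 with an estimated correlation, and fry's test for change in either direction 0.011, with all 4 inhibitor libraries below the placebo mean. The camera call was lost without injured inhibitor 2 (-0.46) or 3 (-0.39) or injured placebo 1 (-0.42) or 4 (-0.33). In injured placebo 1, Dbp (13.4 CPM) and Nfil3 (50.3) lay within the ranges of injured inhibitor libraries (6.31 to 14.8 and 36 to 65.6). Per1 (32.7) lay above their range (7.73 to 19).

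Camera called 23 of 35 lists in this comparison, 8 higher and 15 lower, and fry's directional test none (smallest adjusted p = 0.19). Also not past the threshold were progenitor (mean -0.31, adjusted p = 0.084), tendon (-0.59, 0.16), joint lining (-1.66, 0.43), adipocyte (0.30, 0.38), Schwann cell (-0.08, 0.83), red blood cell (-0.15, 0.90), autophagy (0.05, 0.23), proteasome (-0.05, 0.085) and fast-twitch genes (0.10, 0.16). Adipocyte (-0.35) and atrophy genes (-0.14) were called without the 4 libraries high in joint markers. Median, mean and test differed in sign for the Schwann cell and red blood cell lists. Of single genes, edgeR called 0 of 15411 (smallest adjusted p = 0.1, for Kcnc1), with 2289 at unadjusted p under 0.05, 897 higher and 1392 lower. By other tools, DESeq2 called 255 genes (100 higher, 155 lower), limma-voom with quality weights 1348 (520 higher, 828 lower) and limma-voom with the correlation within animals 0. Without injured placebo 4, edgeR called 39 genes, 17 higher and 22 lower.

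Inhibitor and placebo were also compared in healthy quadriceps, which asks what CSF1-R inhibition changed without the injury. Clock genes differed again: Per3 averaged 32.0 ± 9.73 CPM with placebo and 13.4 ± 3.34 CPM with inhibitor (SD, n = 4), a log2 difference of -1.25 ± 0.27, Per2 7.22 ± 3.27 and 2.52 ± 0.754 CPM, and Npas2, an activator of the clock, 1.06 ± 0.432 and 3.26 ± 0.864 CPM, a difference of 1.62 ± 0.38. As in injured muscle, 11 of 17 clock genes were lower and 6 higher (mean -0.38). When adjusted over the list alone, 8 lower and 2 higher passed. The limbs are of the same animals, so the agreement is no independent repeat. In healthy placebo 1, Dbp (16 CPM) lay in the range of healthy inhibitor libraries (7.35 to 19.1). Per1 (38.9) lay above theirs (12 to 23.3). Markers of fibro-adipogenic progenitors were higher for 11 of 16 (mean 0.13), for example Gsn, an actin-severing protein, at 472 ± 143 and 666 ± 135 CPM, and genes of oxidative phosphorylation for 39 of 46 (0.07). Macrophage markers were lower for 25 of 30 (mean -1.02), but the list was not past the threshold (camera adjusted p = 0.77). The mean was 0.56 without healthy placebo 4, high in joint markers (adjusted p = 0.063), and 0.06 without all 4 such libraries (0.079). Csf1r averaged 12 ± 12.9 and 8.34 ± 4.63 CPM, Cd68 4.27 ± 6.61 and 1.27 ± 0.933 CPM and C1qa 9.71 ± 13.2 and 5.60 ± 4.42 CPM. In healthy placebo 4, C1qa was at 29.4 CPM against 1.87 to 4.79 CPM in the other 3 placebo libraries.

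Camera adjusted p values were 0.0058 for clock genes, 0.0013 for progenitor markers and 0.018 for oxidative phosphorylation. With an estimated correlation the adjusted p values were 0.69, 0.94 and 0.94. Against the placebo mean, the direction held in 4, 3 and 2 of the 4 inhibitor libraries. Fry's test for change in either direction gave 0.024 for the clock list. The clock call was lost without healthy placebo 1 (-0.35) or 3 (-0.32). The progenitor mean was -0.07 without healthy placebo 1 and -0.02 without healthy placebo 3, neither past the threshold, 0.57 without healthy placebo 4, 0.02 without healthy inhibitor 1 and 0.24 without healthy inhibitor 4. The oxidative phosphorylation call was lost without healthy inhibitor 1 (0.01) or 3 (0.06) or healthy placebo 1 (0.04) or 4 (0.00), and its mean was 0.11 without healthy inhibitor 2 or 4 and 0.16 without healthy placebo 3. When the 4 libraries high in joint markers were left out, 12 lists were called. Progenitor markers averaged 0.46 (adjusted p = 2e-10) and clock genes -0.39 (0.0033), and the oxidative phosphorylation call was reversed (-0.06, adjusted p = 0.023). The other 9 were class II (0.62), interferon (0.34), matrix (0.35), tendon (0.22), endothelial (-0.11), red blood cell (-0.71), myogenesis (0.19), tricarboxylic acid cycle (-0.10) and mitochondrially encoded genes (-0.17).

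Of 35 lists 3 were called in healthy quadriceps, 2 higher and 1 lower, with 7 without healthy inhibitor 2 or 4, 1 without healthy placebo 1, 8 without healthy placebo 2 and 7 without healthy placebo 4. Median, mean and test differed in sign for 10 uncalled lists: class II, neutrophil, B cell, cytokine, interferon, complement, endothelial, denervation, fast-twitch and mitochondrially encoded genes. EdgeR called 0 of 15411 genes (smallest adjusted p = 0.555, for Irf2bp2), with 514 at unadjusted p under 0.05, 201 higher and 313 lower, where chance gives 771. DESeq2 called 12 genes, 5 higher and 7 lower, and limma-voom 0 both with quality weights and with the correlation within animals. Without healthy placebo 1, edgeR called 1.

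**Figure D3:**
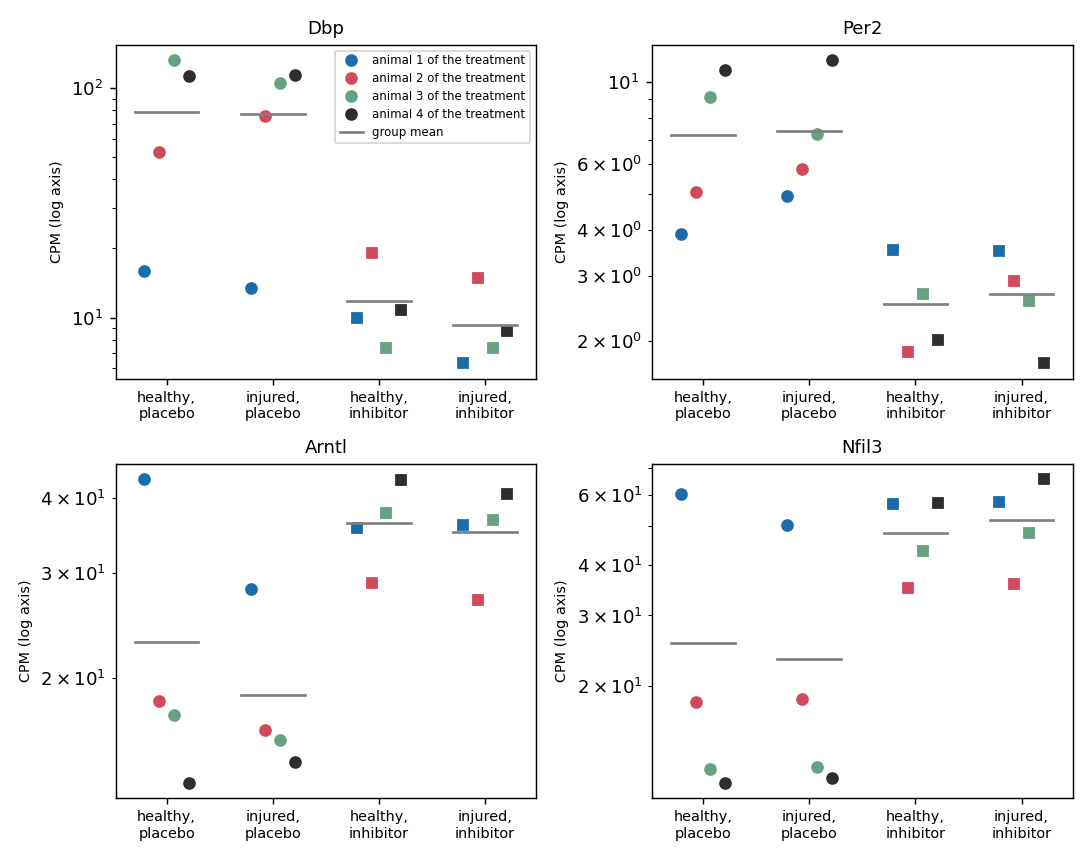
Levels of the clock genes Dbp, Per2, Arntl and Nfil3 in CPM (vertical log axes) in each of the 16 libraries, by group; each point is 1 library, colours mark the animal within a treatment, circles are placebo, squares are inhibitor and grey lines are group means. Arntl lay between 27 and 42.8 CPM in the 8 inhibitor libraries and at 13.4 to 18.3 CPM in the placebo libraries of animals 2, 3 and 4, with placebo animal 1 at 43.0 and 28.2 CPM.

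The difference between the injury effects under inhibitor and placebo was tested directly, which asks whether CSF1-R inhibition altered the response to injury. The macrophage list differed by a mean of -1.58, with all 30 members more negative under the inhibitor, class II genes by -1.50 (12 of 13), interferon-stimulated genes by -1.0 (all 24), lysosome genes by -0.99 (26 of 27), cytokines by -0.89 (16 of 17) and complement genes by -0.63 (13 of 14). Csf1r itself differed by -1.59 ± 1.12 (SE, n = 4 per group), Bst2 by -1.54 ± 0.61 and Cxcl10 by -3.41 ± 1.24. Camera gave adjusted p values of 1.5e-07, 1.4e-07, 1.1e-09, 1.8e-07, 0.00013 and 0.00046 in this order. The adjusted p = 0.46 with an estimated correlation for macrophage markers and 0.41 for the other 5 lists. The injured minus healthy score lay below the mean of the placebo animals in 4 of 4 inhibitor animals, or in 3 for complement genes. In this comparison, directions in animals are counted against that mean. The macrophage score itself rose with injury in 2 of 4 inhibitor animals, and it fell in placebo animal 4. Adjusted over the list alone, 1 cytokine gene passed. Without healthy placebo 4, high in joint markers, the means of macrophage, class II, lysosome, cytokine and complement genes were -3.15, -2.37, -1.79, -1.94 and -1.26, and without injured placebo 2 that of cytokines was -0.52. In fits that lacked the 4 libraries high in joint markers, the 6 means were -0.58, -1.04, -0.36, -0.36, -0.57 and -0.66, all past the threshold.

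Monocyte and neutrophil markers differed by -1.0 (8 of 9 negative) and -1.75 (all 5), both at camera adjusted p = 0.036, and adjusted p = 0.56 and 0.47 with an estimated correlation, in 3 and 4 of the 4 inhibitor animals. The monocyte call was lost without healthy inhibitor 1 (-0.06), injured inhibitor 2 (-0.82), healthy placebo 1 (-0.68) or 3 (-0.65) or injured placebo 1 (-1.11), 2 (-0.44) or 3 (-0.85), and its mean was -2.38 without healthy placebo 4. Without the 4 libraries high in joint markers it was -0.49 (adjusted p = 0.033). The neutrophil call was lost without any injured inhibitor library (-3.24 to -2.97) or healthy placebo 1, 2 or 3 (-2.68 to -2.62). It was also lost without healthy inhibitor 1 (-0.16) or injured placebo 1 or 2 (-3.20 and -0.80). It held in 6 other fits (-3.92 to -3.25). Tested members could change, so lost calls and shifts cannot be put down to the library left out. With the animal as a block, the neutrophil adjusted p was 0.075.

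Myogenesis genes differed by -0.85 (18 of 20 negative) and denervation-responsive genes by -0.75 (15 of 19), with Myog at -2.54 ± 0.91 (SE, n = 4 per group), Musk at -0.74 ± 0.28 and Chrna1 at -1.12 ± 0.43. Oxidative phosphorylation genes differed by 0.23 (all 46 positive), the tricarboxylic acid cycle by 0.26 (all 17), fatty acid oxidation by 0.29 (29 of 30), mitochondrially encoded genes by 0.29 (14 of 15) and glycolysis by 0.17 (22 of 24), with Sdhb, of respiratory complex II, at 0.47 ± 0.20, Ppargc1a at 0.56 ± 0.25 and Slc2a4 at 0.33 ± 0.14. Camera adjusted p values were 0.0011 and 0.013 for the first 2 lists and 3.9e-10, 5.5e-08, 9.6e-09, 0.00019 and 0.00031 for the metabolic lists, with 4 of 4 inhibitor animals on that side of the placebo mean. The adjusted p = 0.41 with an estimated correlation for 5 of these lists, 0.48 for mitochondrially encoded and 0.42 for glycolysis genes. Without the 4 libraries high in joint markers, the myogenesis (-0.09) and denervation (0.05) calls were lost, while oxidative phosphorylation was at 0.29 and the other metabolic means lay at 0.20, 0.18, 0.17 and 0.21, past the threshold. The denervation mean was -1.15 without injured placebo 4. Oxidative phosphorylation averaged 0.14 and glycolysis 0.08 without healthy placebo 3, and without injured placebo 1 fatty acid oxidation was at 0.47, mitochondrially encoded genes at 0.58 and glycolysis at 0.11 with the call lost. Without injured placebo 2 the cycle was at 0.16, fatty acid oxidation at 0.15 and mitochondrially encoded genes at 0.14, the last also at 0.14 without healthy placebo 2 and 0.16 without injured inhibitor 2.

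Progenitor markers differed by -0.43 (15 of 16 negative), matrix genes by -0.24 (35 of 47), tendon markers by -0.59 (10 of 11), cell cycle genes by -1.04 (26 of 28), ribosomal protein genes by -0.15 (39 of 45), proteasome genes by -0.10 (30 of 33), stress response genes by -0.16 (17 of 22), immediate early genes by -0.19 (20 of 25) and endothelial markers by 0.21 (14 of 15). Cxcl14, a chemokine gene expressed by progenitors, differed by -0.78 ± 0.22 (SE, n = 4 per group), and Psma7, a proteasome subunit, by -0.41 ± 0.14. Camera adjusted p values were 1.1e-05, 0.00046, 0.036, 0.0009, 0.0053, 0.00065, 0.04, 0.026 and 0.00034 in this order. With an estimated correlation the adjusted p values were 0.41, 0.65, 0.62, 0.57, 0.66, 0.46, 0.41, 0.53 and 0.41. Against the placebo mean, the direction held in 4 of 4 inhibitor animals, or 3 for tendon, stress response and immediate early genes, and 1 progenitor gene passed when adjusted over the list alone.

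Several of these 9 calls were lost or moved in fits that leave out single libraries. Without healthy placebo 4 the means of progenitor, matrix, tendon, cell cycle and immediate early genes were -0.87, -1.80, -0.89, -1.90 and -0.29, and the proteasome call was lost (-0.06). Without injured placebo 2 the calls of matrix (0.33), tendon (-0.27), cell cycle (-0.46), ribosomal (-0.02), stress response (-0.12) and immediate early genes (-0.05) were lost. Without healthy placebo 1 those of matrix (0.04), tendon (-0.32) and ribosomal genes (-0.09) were lost and the progenitor mean was -0.23, and without healthy placebo 3 those of stress response (-0.15) and immediate early genes (-0.08) were lost, with matrix at 0.00, progenitors at -0.28, proteasome at -0.16 and ribosomal genes at -0.24. Without injured placebo 1 the stress response (-0.22) and immediate early (-0.11) calls were lost, with matrix at -0.47, ribosomal genes at -0.26 and endothelial markers at 0.33. Without injured placebo 3 the tendon (-0.37), ribosomal (-0.03) and stress response (-0.15) calls were lost, with matrix at -0.11 and endothelial markers at 0.13. Without healthy placebo 2 the ribosomal (-0.09) and stress response (-0.20) calls were lost, with matrix at -0.04 and proteasome at -0.06, and without injured placebo 4 matrix was at -0.49, ribosomal genes at -0.24, stress response genes at -0.26 and immediate early genes at -0.33. Of the inhibitor libraries, leaving out healthy 1 ended the tendon (-0.49), stress response (-0.17) and immediate early (-0.06) calls with matrix at -0.10, healthy 3 the tendon (-0.44) and stress response (-0.16) calls with matrix at -0.15, healthy 4 the tendon call (-0.60) with stress response genes at -0.26, injured 2 the stress response call (-0.16), injured 3 the stress response (-0.22) and immediate early (-0.13) calls with matrix at -0.46, and injured 4 the tendon call (-0.42) with stress response genes at -0.30. With the 4 libraries high in joint markers left out, the ribosomal call was reversed (0.25, adjusted p = 6.5e-05). The tendon (0.19), cell cycle (0.31) and immediate early (0.10) means were above 0 but not past the threshold, matrix was at -0.04, and the endothelial (0.11), proteasome (-0.06) and stress response (-0.09) calls were lost. With the animal as a block, the stress response adjusted p was 0.087.

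Clock genes did not pass in this comparison (mean -0.05, median 0.02, camera adjusted p = 0.86), and the signs of median, mean and test also differed for the slow-twitch and red blood cell lists. Leaving out the 4 libraries high in joint markers, 5 further lists were called: adipocyte (-0.88), Schwann cell (-0.35), red blood cell (0.49), atrophy (-0.21) and slow-twitch genes (1.24). With all libraries, camera called 24 of 35 lists, 6 higher and 18 lower, and fry's directional test none (smallest adjusted p = 0.52). Of single genes, edgeR called 0 of 15411 (smallest adjusted p = 0.998, for Apod). At unadjusted p under 0.05 there were 423, 210 higher and 213 lower, fewer than the 771 that chance gives. DESeq2 and limma-voom with quality weights called 0. Without both libraries of placebo animal 4, edgeR called 1.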

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

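The tests of technical explanations in this part were all chosen after the results were seen. Within groups of 4 libraries, 34 of 332 groups of values of 83 genes and 8 of 140 groups of list scores held a library whose gap to the nearest other exceeded Dixon's 95% critical value, where chance gives about 1 in 20 groups.

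Healthy placebo 4 stood above the other 3 libraries of its group for genes of macrophages, monocytes, antigen presentation and matrix. Its levels in CPM were 13.4 for Adgre1, 29.4 for C1qa, 14.1 for Cd68, 17.5 for Ccr2, 8.33 for Fcer1g, 10.3 for Itgam, 4.41 for Tyrobp, 6.75 for Cxcl16, 0.529 for Cxcl10, 8.95 for Bst2, 2.87 for Ciita, 5.07 for H2-DMa, 2090 for Col1a1, 1870 for Col3a1, 41.4 for Cthrc1, 5.69 for Timp1, 18.3 for Runx1 and 0.75 for Ccnb2. Injured inhibitor 3 was likewise high in its group for Ccr2 (7.81), Col1a1 (208), Col3a1 (325), Fcer1g (2.27) and Timp1 (1.45), with a matrix score of 0.31 and a B cell score of 0.49. Injured inhibitor 2 was low for Tgfbi (11.4 CPM) and in its monocyte (-1.24) and cytokine scores (-0.71). Healthy inhibitor 1 was high in its neutrophil (1.60), joint lining (1.59) and ribosomal scores (-0.01), and injured inhibitor 1 in its red blood cell score (0.51).

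Muscle and clock genes gave the remaining single libraries. Healthy placebo 2 was high for Myh1 (7730 CPM) and Sdhb (393), healthy placebo 3 high for Pfkm (3440) and low for Npas2 (0.416), and injured placebo 1 low for Mylpf (2630) and Pvalb (3290). Injured placebo 2 was high for Rnf213 (53.5), injured placebo 4 high for Per1 (53.6), healthy inhibitor 4 low for C3 (50.7) and injured inhibitor 4 low for Casq2 (21).

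The injury effects differed between treatments by camera with its preset correlation for 24 lists, none of them with an estimated correlation. The median log2 differences, inhibitor minus placebo, were -1.56 for macrophage, -0.71 for monocyte, -1.62 for class II, -1.24 for neutrophil, -0.75 for cytokine, -0.81 for interferon, -0.63 for complement and -0.89 for lysosome genes. They were -0.47 for progenitor, -0.27 for matrix, -0.51 for tendon, 0.18 for endothelial, -0.56 for myogenesis, -0.09 for proteasome and -0.74 for denervation genes. Metabolic lists gave 0.16 for glycolysis, 0.24 for oxidative phosphorylation, 0.30 for fatty acid oxidation, 0.24 for the tricarboxylic acid cycle and 0.37 for mitochondrially encoded genes, and ribosomal genes -0.15, cell cycle -1.04, stress response -0.15 and immediate early genes -0.23. Esrra moved in opposite directions in all animals of the 2 treatments, by 0.47 on the log2 scale, and edgeR's test of this difference gave an adjusted p of 0.998.

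Macrophage genes were higher in injured than in healthy quadriceps with placebo, except in placebo animal 4. Without the 4 libraries high in joint markers the mean was 1.11 against 1.57, between the bounds set for joint tissue as the source and against it, so that RNA of joint tissue cannot be told apart from a change within the muscle. An exchange of the limbs of placebo animal 4 could place its macrophage scores with the other animals, but its denervation scores, -0.04 in the healthy and -0.48 in the injured limb, met only part of what an exchange needs and cannot be told apart from animal variation. The injury itself stays open as an untested biological explanation.

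Clock genes differed between treatments in both limbs, but not in all animals alike. In placebo animal 1, Dbp was at 16 and 13.4 CPM and Nfil3 at 60.1 and 50.3 CPM in the healthy and injured limb. The inhibitor libraries held 6.31 to 19.1 and 35.2 to 65.6 CPM, and the other placebo libraries 52.8 to 133 and 11.5 to 18.6 CPM. Per1 in this animal (38.9 and 32.7 CPM) lay with placebo, above the 7.73 to 23.3 CPM with inhibitor. RNA of joint tissue as the whole cause is argued against by the fit without the 4 libraries high in joint markers. There the mean of the 17 clock genes was -0.54 (camera adjusted p = 0.0021) in injured and -0.39 (0.0033) in healthy quadriceps. With all libraries the means were -0.44 and -0.38. RNA of other tissues was not tested. The limbs of an animal lay closer in clock genes than pairings of different animals, with a mean gap per gene of 0.31 against 0.46 on the log2 scale and an exact share of 0.00521 of the possible pairings, as collection at different times of day may give, but any cause acting on whole animals predicts the same and the labels state no times. An effect of the inhibitor on the clock stays open and untested.

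Oxidative genes were higher with inhibitor in injured quadriceps, by 0.30 (SE 0.11, exact permutation p = 0.0571). A lower share of muscle RNA in the placebo libraries could give this: the difference net of fast-twitch genes was 0.16 (SE 0.16), which leaves it unresolved, and the explanation cannot be told apart. With the slow-twitch score as a covariate the difference was 0.26 (SE 0.11), just past a bound set after the results were seen. This argues against more slow fibres in the inhibitor pieces as the whole cause, only as far as the score measures such fibres. An effect of CSF1-R inhibition stays open and untested.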

How the results depend on the processing

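The fits without the 4 libraries high in joint markers, the 3 high in macrophage markers, or both libraries of an animal were chosen after seeing the data. Of 149 gene results 29 changed sign in some fit and 57 passed the threshold in some fit; of 82 called list results 48 kept camera's direction and call in all planned fits and 34 lost the call in at least 1, with camera's direction turned for 1 of them. The mean changed sign in a planned fit for 5 of the 82, 4 of which lost the call. Scaling moved the median of all genes by less than 0.1. The cause was not tested for any of the following. Gene counts of 0 became 3 without injured placebo 4 and 971 without placebo animal 4 for injury with placebo, and 1 by DESeq2 for injury with inhibitor. For the inhibitor in injured quadriceps they became 255 by DESeq2, 1348 by limma-voom with quality weights and 1 with the replicate number as a block. For the inhibitor in healthy quadriceps they became 12 by DESeq2, and for the difference 1 without placebo animal 4. Over the fits that leave out 1 library, the gene counts ranged from 0 to 3, 0 to 0, 0 to 39, 0 to 1 and 0 to 0 in the order of the report, and the list counts from 19 to 26, 5 to 10, 20 to 24, 1 to 8 and 18 to 25. Camera with an estimated correlation and fry's directional test called 0 lists in every comparison. The 25 lists of injury with placebo became 16 without the joint-high libraries (12 shared in the same direction, 2 in the opposite) and 15 without placebo animal 2 (13 and 1). The 7 of injury with inhibitor became 11 by DESeq2 (7 shared), 13 without the joint-high libraries (6 shared), 11 without inhibitor animal 1 (7 shared) and 3 without inhibitor animal 2 (2 shared). The 23 of the inhibitor in injured quadriceps became 14 without the joint-high libraries (10 shared in the same direction, 2 in the opposite). The 3 of the inhibitor in healthy quadriceps became 5 with no filter, 11 by DESeq2, 7 with only the 8 libraries and 7 with the replicate number as a block, with 3 shared each, and 12 without the joint-high libraries, with 2 shared in the same direction and 1 in the opposite. For injury with placebo, means changed sign for fatty acid oxidation without healthy placebo 2 (0.04), injured placebo 2 (0.09) or injured placebo 3 (0.01), with -0.23 to 0.09 over the fits that leave out 1 library, and without placebo animal 2 (0.18) or 3 (0.01). Neutrophil markers did so in 6 planned fits (-0.46 to -0.23) and without placebo animal 1 (-0.22), 2 (-0.58) or 3 (-0.20), and matrix genes without injured placebo 2 (-0.15, still called as higher by camera) or placebo animal 2 (-0.34). Without placebo animal 2, so did the tricarboxylic acid cycle (0.05) and mitochondrially encoded genes (0.13). Without the joint-high libraries the calls of fatty acid oxidation (0.16) and ribosomal genes (-0.16) were reversed, and uncalled means changed sign for cell cycle (-0.12), tendon (-0.04), slow-twitch (-0.05) and mitochondrially encoded genes (0.01). In this fit the calls of matrix (0.30) and ribosomal genes (0.23) were reversed for the inhibitor in injured quadriceps, with endothelial (0.00), cell cycle (0.28) and denervation genes (0.08) turned but not called. That of oxidative phosphorylation (-0.06) was reversed in healthy quadriceps, where progenitors turned without healthy placebo 1 (-0.07) or 3 (-0.02). For the difference, ribosomal genes were reversed (0.25) and tendon (0.19), cell cycle (0.31), immediate early (0.10) and denervation genes (0.05) turned uncalled without the joint-high libraries. Matrix genes turned without healthy placebo 1 (0.04), injured placebo 2 (0.33) or placebo animal 2 (0.52) or 3 (0.13), and ribosomal (0.04) and mitochondrially encoded genes (-0.01) without placebo animal 2. The animal block called 26 lists for injury with placebo, 24 of them shared, lost neutrophil and gained pericyte and clock lists, lost neutrophil and stress response lists for the difference, and changed no other call. The neutrophil list could not be tested without the joint-high libraries.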

Other observations

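The splits in this part were planned; the splits among them that part all pairs were counted after the results were seen. Each comparison was set against the 35 splits of its 8 libraries, or for the difference of the 8 animals, into groups of the same sizes, the real one included, for the counts of edgeR and camera. With a real count of 0 genes past adjusted p 0.05, all 35 splits give as many by definition, so this count tests nothing; the highest other counts were 1933, 1, 0, 0 and 1 in the order of the report. Chance could not be excluded for the other counts. For injury with placebo, 17 splits gave as many genes at unadjusted p under 0.05 as the real 1116 (highest other 4598), and 3 as many lists as the real 25 (30). For injury with inhibitor, these were 21 for 202 (809) and 26 for 7 (16). For the inhibitor in injured quadriceps they were 4 for 2289 (2485) and 4 for 23 (27), and in healthy quadriceps 23 for 514 (2118) and 35 for 3 (21). For the difference they were 18 for 423 (2565) and 5 for 24 (29).

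The splits with most calls point to a structure of the placebo samples, the cause of which was not tested. Of the 5 splits that placed injured placebo 2, injured placebo 3 and healthy placebo 4 on the same side, 4 called 1933, 1724, 1616 and 1598 genes by edgeR and the fifth 0, against 0 for the real split; these 3 libraries are high in joint markers. The split with 1724 calls is the one that exchanges the limbs of placebo animal 4. Of the 8 splits that part all 4 pairs, 4 gave as many genes at unadjusted p under 0.05 and 2 as many lists for injury with placebo (highest other 4075 and 30), and 3 and 8 did so for injury with inhibitor (354 and 16).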
